A study of Homo sapiens with 72 samples.

How the data were processed

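RNA was measured in 72 cultures of human peripheral blood monocytes that had been differentiated in vitro. The design crossed 6 cell types, a coating of fibronectin at 5 µg/mL or PBS alone, and the anti-ILT3 antibody 16C5 or an anti-KLH control antibody at 10 µg/mL, which gave 24 groups of 3 libraries. The 3 libraries of each group came from 3 healthy donors, and the replicate number in the labels names the donor. Libraries were made with a directional total-RNA kit, per the labels' protocols.

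The authors deposited one table of gene counts, whole numbers of reads per gene that had not been normalised, with 26364 gene symbols and one column per library. Trim Galore, STAR 2.6.0a, featureCounts 1.6.2 and edgeR 3.22.3 and the genome build hg19 are named per the submitters' processing notes. The gene annotation, the strand setting of the counting and any filters are not given in the sources used here. An antisense gene and its partner are therefore not told apart with certainty, and genes with near-identical copies, such as the FCGR1 and FCGR3 genes, the metallothioneins, CCL3 and CCL4, are uncertain because their reads could have been shared. Every value column was used, and no row without a gene name was found. No mitochondrial genes were in the table, so a fixed list of these as a sign of RNA quality had no members, and the same held for a list of immunoglobulin chains.

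The reference supplied for this work is GRCh38, another build than the authors' hg19. It served only for gene types, older symbols and the GC content and transcript length used in one correction, and no coordinates are given. A gene type was found for 25255 of the 26364 symbols (95.8%) and for 14307 of the 14580 tested genes (98.1%).

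Total counts per library ran from 3968752 to 58529141, with a median of 24567043. The shallowest library, donor 3 of monocyte-derived dendritic cells on fibronectin with 16C5, stood apart from the next at 9883961. The 12 libraries of donor 3 with 16C5 were shallower, with a median of 14189038, than the 12 of that donor with the control antibody, with a median of 23904848. No libraries were identical, and in all 72 pairs of libraries within groups the counts differed by more than sampling noise (the smallest chi-square per degree of freedom over genes was 12.2).

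Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and F test, robust dispersion). All 72 libraries entered a single fit with one mean per group. Genes were kept by edgeR's filterByExpr on the 24 groups, which left 14580 genes holding 99.99% of the counts, and libraries were scaled by TMM factors, which lay between 0.93 and 1.08. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05. A standard error (SE) of a log2 fold change is the absolute log2 fold change divided by the square root of the F statistic. Levels are TMM-normalised CPM values, given as mean ± SD over 3 libraries, and log2 CPM values used a prior count of 2. For genes with 0 counts in every library of a group, a lower bound on the fold was computed against a floor of 3 counts over the group, which covers counting error only. For genes with 1 to 3 counts in a group the levels are given without a fold.

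No model was stated in the sources used here, so the donor was left out of the main model and added as a block in an alternative. The libraries are paired by donor, and the main model ignores this pairing, so differences between donors stay in its error. The 81 genes called in tolerogenic dendritic cells and followed later come from that model. Without any effect, a share of about 0.05 of the tested genes is expected at an unadjusted p under 0.05. Most comparisons of coating or antibody gave fewer. The exceptions were the anti-ILT3 antibody on fibronectin in tolerogenic dendritic cells, in M1 macrophages and as a mean. Where it called no gene, the main model therefore does not show that no gene changed. Libraries with the same number come from the same donor. The pairing was checked on deviations of log2 CPM from the group means, without sex-linked markers. The median correlation between libraries of the same donor was 0.41, 0.42 and 0.35 for donors 1, 2 and 3, and −0.20 between donors. Subtracting group means forces a negative value between donors wherever libraries of the same donor correlate, so it adds no separate evidence. The most similar library was from the same donor for 72 of 72 libraries. The value with the donor block is printed beside a result where it changed a call or moved a count by more than 1.5 times.

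The comparisons were fibronectin against PBS under the control antibody, 16C5 against control antibody on each coating, and the difference of these 16C5 effects between coatings, each within the 6 cell types and as a mean over them. Tests over the 6 cell types asked whether the fibronectin effect and the 16C5 effect on fibronectin differed between types. In cultures on PBS with control antibody, 5 comparisons between cell types were made.

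The genes named follow a rule written before the data were examined. LILRB4, which encodes ILT3, and FN1, which encodes fibronectin, are named by it in every comparison. In each direction the rule takes the 8 protein-coding genes with the largest absolute log2 fold change among those past the threshold, with a mean of at least 5 CPM over the compared groups and the same sign in all 3 donors. Where fewer than 4 passed, it takes up to 4 genes with the smallest p and the same sign in all donors, given as not past the threshold. From each described list it takes up to 4 members with the smallest p, of which some are not reported here. The rule was applied in full to the comparisons between cell types, to the comparisons in tolerogenic dendritic cells and to the means over cell types. In the other comparisons within a cell type, where no gene passed, the genes it takes are given for 16C5 on fibronectin in monocyte-derived dendritic cells and otherwise mainly counts and gene lists are described, a choice made after the results were seen. Sex-linked markers, most HLA genes, receptor segments and genes with common whole-gene deletions were never named, since donors can differ in them. Genes that make up a count of 5 or fewer and lie outside the rule are said to have been chosen after their values were seen.

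A set of 34 gene lists was fixed before the data were examined, of which 32 had at least 5 tested members. Which lists are described for a comparison was chosen after their results were seen. Lists were tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, with camera's estimated correlation and with fry. Counts "adjusted over the list alone" use Benjamini-Hochberg values within the list.

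Alternatives were the donor block, DESeq2 1.42.0 size factors or library size alone as scaling, DESeq2's Wald test, limma-voom, no count filter or a stricter one (at least 1 CPM in at least 6 libraries), fits to the libraries of the compared cell types alone, each donor left out, an absolute log2 fold change of at least 1, and a correction for GC content and transcript length with the donor block (values for 13692 of 14580 genes, 93.9%). The follow-up of the 81 genes called in tolerogenic dendritic cells rests on genes selected in these data. Chosen after the data were seen were a donor term within each cell type, a fit without the shallowest library, tests of gene lists without one library at a time, and tolerogenic dendritic cell libraries thinned to equal depth.

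The fits were tested on simulated counts built on the tolerogenic dendritic cell comparison of 16C5 on fibronectin, with 14490 genes tested and known changes in both directions. Of the genes changed 1.5-fold, edgeR recovered 23.9% without the donor block and 40.3% with it. Of those changed 2-fold it recovered 53.0% and 68.2%, and of those changed 4-fold 70.8% and 86.2%. Without the block 0 of 97 calls were false, and with it 9 of 137.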

Results

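Gene counts were available for 72 libraries of human monocyte-derived cells from 3 healthy donors. Monocytes had been turned into monocyte-derived dendritic cells (moDC; GM-CSF and IL-4), tolerogenic dendritic cells (tolDC; the same followed by vitamin D3 and dexamethasone), M0 macrophages (M-CSF), and macrophages polarised with interferon gamma and lipopolysaccharide (M1), IL-4 (M2a) or IL-10 (M2c). Each cell type was grown on PBS-treated or fibronectin-coated plastic with either the anti-ILT3 antibody 16C5 or an anti-KLH control antibody, and was harvested on day 7. ILT3, encoded by LILRB4, is an inhibitory receptor of myeloid cells. Each of the 24 groups held 1 library per donor (n = 3), with 3968752 to 58529141 counts per library. The comparisons ask which genes each cell type expressed, whether fibronectin changed them, and whether blocking ILT3 changed them on either coating.

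LILRB4 RNA was highest in tolDC and M1 macrophages. On PBS with control antibody it was 750 ± 111 CPM (SD, n = 3) in tolDC, 629 ± 153 in M1, 247 ± 122 in M2c, 220 ± 57.7 in moDC, 179 ± 117 in M2a and 129 ± 71.3 in M0. It rose in tolDC over moDC by a log2 fold change of 1.77 (SE 0.444, edgeR adjusted p = 0.004) and in M1 over M0 by 2.29 (SE 0.452, adjusted p = 4.86e-05), in 3 of 3 donors each. The tolDC call was lost without donor 3 (log2 fold change 1.79, adjusted p = 0.12), and with the donor block it was 7.17e-06. M2c and moDC lay above M0 by 0.94 and 0.77, which passed the threshold only with the donor block (edgeR adjusted p = 0.158 without and 0.00889 with it in M2c, 0.164 and 0.0204 in moDC). For M2a over M0 the value was 0.47 (adjusted p = 0.653). Neither coating nor antibody changed LILRB4 past the threshold in any cell type.

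**Figure D1:**
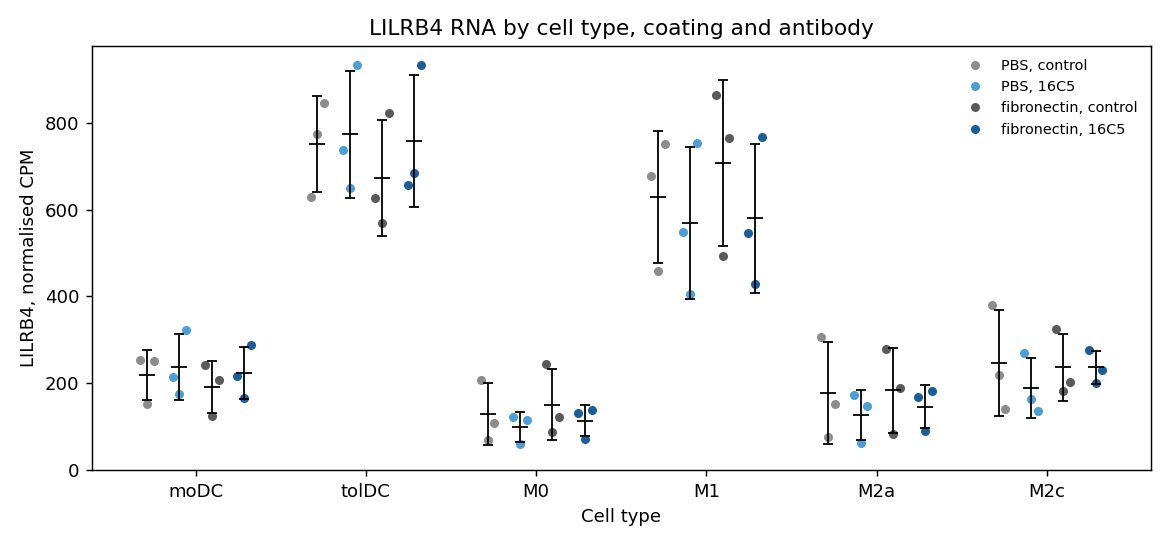
LILRB4 RNA in normalised CPM (y axis) for each cell type (x axis), coating and antibody. Points are libraries, 1 per donor, and bars are mean ± SD (n = 3). Means on PBS with control antibody were 750 CPM in tolDC and 629 in M1, against 129 in M0.

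Tolerogenic dendritic cells were compared with moDC on PBS with control antibody. CYP24A1, which inactivates vitamin D, was at 1850 ± 1960 CPM in tolDC and 0.494 ± 0.496 in moDC (log2 fold change 11.8, SE 1.82, edgeR adjusted p = 4.87e-06). The monocyte receptor gene CD14 rose by 6.42, to 560 ± 310 CPM from 6.54 ± 3.79, and the antimicrobial peptide gene CAMP by 6.24, to 48.4 ± 27.7 from 0.649 ± 0.517. Carbonic anhydrase CA2 rose by 4.56. The other genes with the largest rises were CEMIP (7.45), IQSEC3 (7.10), SHE (6.69), ceruloplasmin CP (6.68) and PXDN (6.64), with NR1I2 at 10.2 ± 5.09 CPM against 0.0276 ± 0.0478. Those that fell most were CLDN1 (−8.34), LAMP3 (−5.53), the IgE receptor gene FCER1A (−5.43), CGNL1 (−5.21), GGT5 (−4.98), DHRS2 (−4.84) and DMWD (−4.70), and P3H2 was at 0.0433 ± 0.039 CPM against 12.2 ± 19.8. FN1 was at 609 ± 517 CPM against 225 ± 236 (1.44, adjusted p = 0.468).

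Of 24 vitamin D and glucocorticoid response genes, 12 rose and 1 fell in tolDC (15 and 1 adjusted over the list alone; camera adjusted p = 4.17e-10, and adjusted p = 0.0162 with an estimated correlation), and the one that fell, STEAP4, was chosen after its values were seen. Of 15 dendritic cell markers, 8 fell and 0 rose (9 adjusted over the list alone; camera adjusted p = 4.5e-09, and 0.00598 with an estimated correlation), among them CD1A, CD1B and CD1C at log2 fold changes of −4.65, −2.91 and −4.40 and the transcription factor gene IRF4 at −2.73. Of 19 antigen presentation genes, which share the CD1 genes with that list, 7 fell and 2 rose (9 and 2 adjusted over the list alone; adjusted p = 0.022 with an estimated correlation), and those that rose, CTSS (0.65) and CD1D (1.72), were chosen after their values were seen. Of 19 cholesterol synthesis genes, 10 fell (12 adjusted over the list alone), including MVD (−1.38), SQLE (−0.81), SREBF2 (−0.63) and IDI1 (−0.78), but the list's camera call was lost at adjusted p = 0.0822 with an estimated correlation. Of 26 tolerogenic and suppressive genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.0377 with an estimated correlation), led by the glucocorticoid-induced TSC22D3 (1.90), VSIG4 (5.32) and LGALS9 (1.38), and ARG1 was at 1.29 ± 0.814 CPM against 0.0252 ± 0.0436. CD200R1, chosen after its values were seen, was the one that fell (−1.21). With the donor block, that list's adjusted p was 0.182 with an estimated correlation, and without the block it was 0.0613, 0.0697 and 0.0807 without the moDC libraries of donors 1 and 3 and the tolDC library of donor 2. Ribosomal protein genes, kept as a sign of RNA quality, moved with these groups, with 13 of 18 higher in tolDC (median log2 fold change 0.75; adjusted p = 0.428 with an estimated correlation). In all, 990 genes rose and 988 fell among 14580 tested (edgeR), and with the donor block 1720 rose and 1860 fell. Without donor 1 the calls numbered 1153 and without donor 3 they numbered 653.

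M1 macrophages differed from M0 in 5543 genes, of which 2816 rose and 2727 fell (edgeR). IDO1, which degrades tryptophan, was at 1040 ± 111 CPM against 0.352 ± 0.422 (log2 fold change 11.3, SE 1.04, edgeR adjusted p = 5.45e-13). LAD1, CCM2L, MUCL1 and BOC had no counts in M0, and were at least 735-fold, 506-fold, 387-fold and 270-fold higher in M1. MYH11 was at 108 ± 81.6 CPM against 0.0113 ± 0.0195, MT1M at 99.0 ± 42.1 against 0.013 ± 0.0225, and CA12 at 152 ± 83.9 against 0.0363 ± 0.035. HS3ST2 fell by 8.33, to 3.54 ± 1.83 CPM from 1130 ± 183, and ZNF704 (−9.03), COLEC12 (−7.97), CD22 (−7.85), CRHBP (−7.82) and ADRA2B (−7.62) also fell. DNASE2B had no counts in M1 and was at least 337-fold lower, and KLHL13 was at 0.0158 ± 0.0274 CPM against 12.1 ± 4.23. FN1 was at 1.42 ± 0.373 CPM against 1.95 ± 1.18 (−0.52, adjusted p = 0.803).

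Of 21 M1 markers, 19 rose and 0 fell (20 adjusted over the list alone; camera adjusted p = 6.29e-17, and 1.3e-05 with an estimated correlation), including IRF1 (4.56), GBP1 (6.35), CD38 (6.91) and APOL3 (4.99). Of 29 inflammatory cytokine and NF-kB genes, 23 rose (24 adjusted over the list alone), among them SOD2 (3.76), NFKBIA (3.06), NFKB2 (2.73) and IL1A (7.67), and of 32 chemokines 20 rose and 2 fell (20 and 2 adjusted over the list alone), with CXCL1 at 5.96, CXCL5 at 9.32 and CCL8 at 6.91 and CCL19 at 42.7 ± 33.2 CPM against 0.0113 ± 0.0195. The chemokine genes that fell were CXCL12 (−3.34) and the receptor gene CXCR4 (−1.48), and the lysosomal genes that rose were CTSL (1.44) and ATP6V1H (0.78), all chosen after their values were seen. The inflammatory and chemokine lists each stood at adjusted p = 0.0559 with an estimated correlation. Of 19 genes listed as IL-10 response markers, 17 rose in M1 as well (17 adjusted over the list alone; adjusted p = 0.00294 with an estimated correlation), including STAT3 (1.24), SOCS3 (5.89), IL4R (1.42) and SLAMF1 (8.57). Of 23 lysosome and phagocytosis genes, 16 fell and 2 rose (17 and 2 adjusted over the list alone), led by the lysosomal acid lipase gene LIPA (−4.79), GPNMB (−3.72), cathepsin K CTSK (−3.02) and TREM2 (−6.54); the adjusted p was 0.215 with an estimated correlation and 0.0332 with the donor block as well.

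M2a macrophages differed from M0 in 858 genes, of which 540 rose and 318 fell (edgeR), and with the donor block in 1994. The IL-4 induced chemokine genes CCL18 and CCL13 rose by log2 fold changes of 7.68 (SE 1.84, edgeR adjusted p = 0.00518) and 7.61 (SE 0.8, adjusted p = 6.98e-10). The low-affinity IgE receptor gene FCER2 rose by 7.57, to 515 ± 107 CPM from 2.63 ± 1.27, and IL17RB (7.50), SOCS1 (6.41), AKAP5 (6.17), RAMP1 (5.99) and CACNB4 (5.91) also rose. FN1 rose by 5.61, to 98.9 ± 82.5 CPM from 1.95 ± 1.18 (SE 1.4, adjusted p = 0.00775). LEP fell to 0.177 ± 0.1 CPM from 11.3 ± 3.53, and SERPINB2 (−5.58), BAALC (−4.51), CD163L1 (−3.96), ADAM28 (−3.96), CD244 (−3.82), ALOX5 (−3.20) and SH3RF3 (−3.09) also fell. Of 24 M2a markers, 17 rose and 0 fell (22 with the donor block, 21 adjusted over the list alone; adjusted p = 8.58e-13 with an estimated correlation), including CISH (5.02) and the monoamine oxidase gene MAOA (5.22). Of 15 dendritic cell markers, 7 rose (9 adjusted over the list alone; adjusted p = 0.00253 with an estimated correlation), with CD209 at 5.35, CD1B at 4.98, CLEC4A at 1.43 and CD1C at 4.45. Of 12 monocyte genes, S100A8 (−2.19), LYZ (−1.20) and CD14 (−1.62) fell (6 adjusted over the list alone; adjusted p = 0.0229 with an estimated correlation, and 0.0568 without the M0 library of donor 2), and VCAN was at −2.32 (adjusted p = 0.089). Without donor 1 there were 316 calls and without donor 3 there were 220.

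M2c macrophages differed from M0 in 2117 genes, of which 1251 rose and 866 fell (edgeR), and with the donor block in 3498. Of the calls 59.1% were higher with TMM, and 49.5% of 2158 with scaling by library size alone. The scavenger receptor gene CD163 rose by 3.32, to 14000 ± 1520 CPM from 1400 ± 274 (SE 0.401, edgeR adjusted p = 1.06e-08). The autotaxin gene ENPP2 (9.57), TNIP3 (9.36), CASP5 (8.06), KREMEN1 (7.63), IL21R (7.14), JAK3 (6.96) and the phospholipid transfer protein gene PLTP (6.96) had the largest rises, with C3orf70 at 11.4 ± 3.43 CPM against 0.0243 ± 0.0212. ADGRE3 (−7.58), APOBEC3A (−6.63), properdin CFP (−4.63), CD22 (−4.18), MYO1A (−3.87), SPTBN1 (−3.77), NAV2 (−3.53) and BAALC (−3.48) fell. FN1 was at 1.4 ± 1 CPM against 1.95 ± 1.18 (−0.61, adjusted p = 0.85), and its sign turned without donor 1 (0.21). Of 19 IL-10 response markers, 16 rose and 0 fell (16 adjusted over the list alone; adjusted p = 1.81e-05 with an estimated correlation), including SOCS3 (6.56), STAT3 (1.04), IL4R (1.51) and SBNO2 (2.75). Of 26 tolerogenic and suppressive genes, 8 rose (10 adjusted over the list alone; adjusted p = 0.00546 with an estimated correlation), among them VSIG4 (4.33), ARG2 (2.06) and TSC22D3 (1.21). Of 20 glycolysis and hypoxia genes, 17 rose (18 adjusted over the list alone), including GAPDH (1.80), PFKP (2.83), LDHA (2.09) and PGK1 (1.73), at adjusted p = 0.0587 with an estimated correlation. Of 13 Fc receptor genes, 5 rose (6 rose and 1 fell adjusted over the list alone), led by FCGR1B (2.42), FCGR1A (1.93), FCGR3A (4.55) and FCGR2C (1.64), whose reads near-identical copies could share, at adjusted p = 0.0905 with an estimated correlation. FCGR2A (2.20) was the fifth that rose and FCGRT (−0.56) the one that fell in the list alone, both chosen after their values were seen. Of the 32 lists tested in M2c, 2 passed with an estimated correlation without the donor block and 3 with it. Without donor 1 there were 1183 calls and without donor 3 there were 1011.

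Monocyte-derived dendritic cells differed from M0 in 5438 genes, of which 2860 rose and 2578 fell (edgeR). The lipid-presenting CD1B rose by 10.6, to 252 ± 86.5 CPM from 0.145 ± 0.0661 (SE 0.704, edgeR adjusted p = 3.99e-17), and CCL13 rose by 10.4. The oxidase gene DUOX1, its maturation factor DUOXA1 and MMP10 had no counts in M0 and were at least 892-fold, 506-fold and 272-fold higher. DHRS2 was at 99.8 ± 109 CPM against 0.013 ± 0.0225, CLDN1 at 71.1 ± 116 against 0.0225 ± 0.039, and FOXQ1 at 66.7 ± 54.3 against 0.0243 ± 0.0212. FN1 rose by 6.79 (SE 1.47, adjusted p = 0.000212). The heparanase gene HPSE fell by 9.67, to 0.35 ± 0.135 CPM from 293 ± 24.1, PID1 fell to 0.046 ± 0.0796 CPM from 29.7 ± 19.5, and FCN1 (−8.80), BAALC (−7.57), LEP (−7.35), SERPINB2 (−7.33), CADM1 (−7.01) and CD14 (−6.34) fell. Of 15 dendritic cell markers, 13 rose (13 adjusted over the list alone; adjusted p = 0.00164 with an estimated correlation), with CD1C at 9.09, IRF4 at 5.04 and CLEC4A at 2.41. Of 24 M2a markers, 23 rose (23 adjusted over the list alone; adjusted p = 5.75e-09 with an estimated correlation), including MAOA (7.52) and CISH (6.18). Of 12 monocyte genes, 7 fell (7 adjusted over the list alone, with 1 risen), among them LYZ (−2.58). The list's adjusted p was 0.0954 with an estimated correlation, and 0.0355 with the donor block as well. CSF1R (1.35), chosen after its values were seen, was the one that rose in the list alone. Of 20 costimulation and maturation genes, 11 rose and 2 fell (11 and 2 adjusted over the list alone), with CD274 at 4.64, CD40 at 3.13, LAMP3 at 9.19, CD48 at −2.01 and TNFSF9, chosen after its values were seen, at −2.00, at adjusted p = 0.358 with an estimated correlation. Ribosomal protein genes moved the other way, with 9 of 18 lower in moDC (median −0.55; adjusted p = 0.739 with an estimated correlation). Without donor 3 there were 3104 calls.

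On fibronectin, 51 genes rose and 30 fell in tolDC with 16C5 (edgeR, 14580 genes tested). CEMIP, a hyaluronan-binding protein gene, rose to 32.3 ± 9.92 CPM from 3.46 ± 2.59 (log2 fold change 3.24, SE 0.656, adjusted p = 0.00923). The complement component gene C3 rose to 56.2 ± 20.8 CPM from 9.67 ± 5.52 (2.55, SE 0.432, adjusted p = 0.00102). The purine enzyme gene AMPD3 rose by 1.42 with the smallest p (SE 0.198, adjusted p = 3.88e-05). MEST (2.91), the TNF receptor adaptor gene TRAF1 (2.59), the GTPase gene RHOC (1.86), TRIP10 (1.63) and MAP7 (1.41) rose as well. CCL26, the chemokine eotaxin-3, fell to 35.1 ± 8.4 CPM from 164 ± 40.0 (−2.22, SE 0.38, adjusted p = 0.00102), and the purine receptor gene P2RY13 fell to 11.1 ± 3.59 from 46.0 ± 7.64 (−2.05). CLIP2 fell to 6.85 ± 4.14 CPM from 19.4 ± 6.64 and CYBB, a subunit of the phagocyte oxidase, to 187 ± 107 from 375 ± 169. CDH26 (−1.80), TMEM150B (−1.32), the epoxide hydrolase gene EPHX1 (−1.05) and KCNE3 (−1.05) also fell. Each of these genes moved the same way in 3 of 3 donors, which the rule for naming them required. LILRB4 was at 758 ± 152 CPM with 16C5 and 672 ± 133 with control antibody (0.17, adjusted p = 0.947), and FN1 at 873 ± 953 against 441 ± 484 (0.99, adjusted p = 0.816).

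With the donor block, 508 genes rose and 281 fell in this comparison, and all 81 genes were among them. Without donor 3 there were 2 calls, C3 and CCL26, with 132 without donor 2 and 45 without donor 1, which held 33 and 23 of the 81. With the block 28 of the 81 passed without donor 3. The median signed log2 fold change of the 81 was 0.983, 0.919 and 1.09 without donors 3, 2 and 1, against 0.975 with all donors, on libraries that had taken part in choosing the genes. In the fit to the tolDC libraries alone there were 2 calls, AMPD3 and, chosen after its values were seen, MSANTD3, at a median of 0.972 for the 81, and with the donor block 2285, which held 80 of the 81. A donor term within each cell type, chosen after the data were seen, gave 2553 calls, all 81 among them. Scaling by library size alone gave 74 calls of which 39.2% were higher, against 63.0% with TMM. DESeq2's Wald test called 216 genes and limma-voom 193, and 40 of the 81 had an absolute log2 fold change of at least 1.

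**Figure D2:**
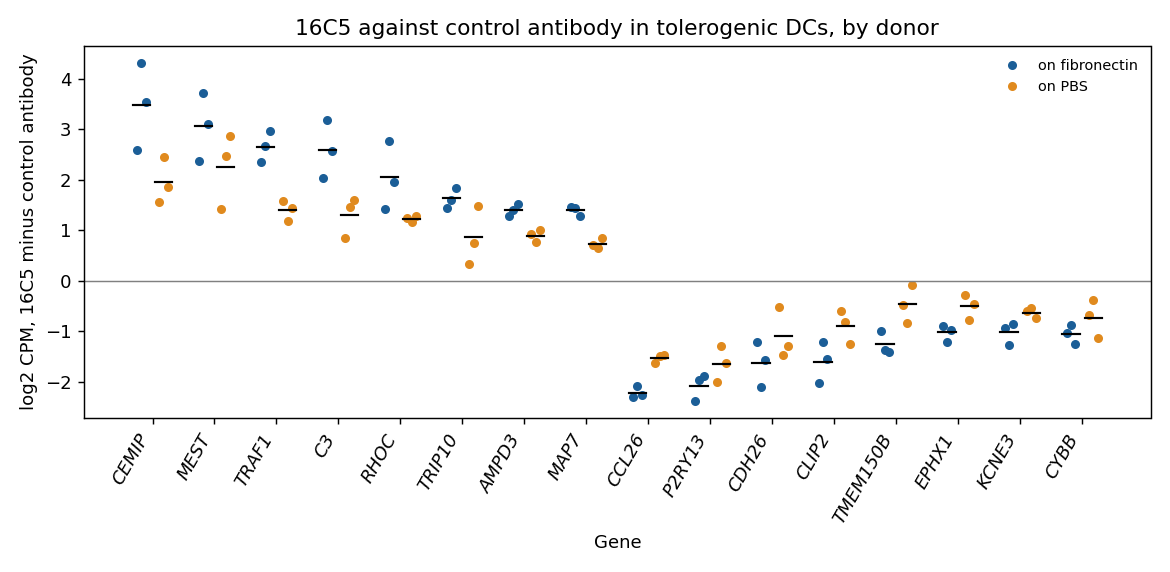
Difference in log2 CPM between 16C5 and control antibody (y axis) in tolerogenic dendritic cells for the genes named by rule (x axis), on fibronectin and on PBS. Points are the 3 donors, whose shared sign on fibronectin the rule required, and lines their means. On fibronectin CEMIP rose by a fitted log2 fold change of 3.24 and CCL26 stood at −2.22.

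Several fixed gene lists shifted in tolDC with 16C5 on fibronectin by camera with its preset correlation, and none of these calls held with an estimated correlation. Costimulation and maturation genes lay higher (median log2 fold change 0.66, 18 of 20 above 0, camera adjusted p = 0.0101; adjusted p = 0.713 with an estimated correlation), with 0 of 20 past the threshold singly or adjusted over the list alone and 3 with the donor block. CD86 was at 485 ± 82.8 CPM against 299 ± 69.3 and SLAMF7 at 96.0 ± 30.4 against 38.6 ± 31.0 (edgeR adjusted p = 0.274 and 0.36, and 0.0264 and 0.0233 with the block). FSCN1 and SLAMF1 stood at 1.49 and 1.27, and CD276 (0.63, adjusted p = 0.0207 with the block) was chosen after its values were seen. Matrix and matrix-remodelling genes lay higher (median 0.91, adjusted p = 0.0217; 0.713 with an estimated correlation). None of the 31 passed over all genes, 1 rose adjusted over the list alone, and 4 rose with the block. These were the protease genes MMP12, which also passed in the list alone, and MMP7, the matrix gene TNC (4.22, 4.47 and 3.71; adjusted p = 0.018, 0.0162 and 0.0497 with the block), and the collagen gene COL6A2 (1.09), chosen after its values were seen. MMP1 stood at 3.19 (adjusted p = 0.132 with the block). Fc receptor genes lay lower (median −0.43, adjusted p = 0.0217; 0.713 with an estimated correlation), with 0 of 13 past the threshold singly or adjusted over the list alone. FCGRT stood at −0.66 (adjusted p = 0.0264 with the block), SYK at −0.33, and FCGR1A and FCGR1B at −0.86 and −0.82. Glycolysis, cholesterol synthesis and oxidative stress lists lay higher (medians 0.33, 0.23 and 0.51), with adjusted p = 0.87, 0.713 and 0.713 with an estimated correlation. Of their members 0, 0 and 1 rose adjusted over the list alone, and 0 over all genes. The leading ones were GAPDH (0.46), ENO1 (0.39), INSIG1 (0.69), MSMO1 (0.42), SLC7A11 (2.71) and TXNRD1 (0.62), of which SLC7A11 passed in the list alone and TXNRD1 and SLC7A11 with the block (adjusted p = 0.00613 and 0.0182).

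Among 19 antigen presentation genes, HLA-DMA and HLA-DMB, which load peptides onto class II molecules, fell by 0.67 and 0.93 (edgeR adjusted p = 0.0102 and 0.00931). Adjusted over the list alone 3 fell, the third being CIITA, the class II regulator (log2 fold change −1.21, adjusted p = 0.157 over all genes and 0.00741 with the donor block). With the block 5 fell, including the cathepsin gene CTSS (−0.50, adjusted p = 0.255 without and 0.0194 with it) and HLA-DOA (−1.32, 0.0444 with it), which was chosen after its values were seen. Among 26 integrin and adhesion genes ITGAL fell by 0.83 (adjusted p = 0.0444), while the fibronectin receptor subunit genes ITGA5 and ITGB1 stood at 0.63 and 0.49 (adjusted p = 0.0805 and 0.181) and passed both adjusted over the list alone and with the block (0.0174 and 0.0264). ITGAV stood at 0.58. That list's camera adjusted p was 0.0554, and 0.0262 with the block, where it was 0.772 with an estimated correlation. Of 32 chemokines CCL26 fell over all genes. CCL3 and CCL4 stood at 2.07 and 2.31 and CCL24 at −2.56, and all 3 passed adjusted over the list alone and with the block (adjusted p = 0.013, 0.0213 and 0.000949). Of 29 inflammatory genes BIRC3 (1.49) passed in the list alone, and BIRC3, TNFAIP3 (1.19) and NFKB2 (0.65) passed with the block. Of 21 M1 markers CYBB fell, as the only member past the threshold over all genes or in the list alone. Ribosomal protein genes had a median of −0.14 and monocyte genes of −0.74, with camera adjusted p = 0.139 and 0.138.

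On PBS, 16C5 called no gene in tolDC in edgeR without a donor term. There were 531 genes at an unadjusted p under 0.05, 0 calls by DESeq2 and 10 by limma-voom. With the block 6 genes rose and 3 fell, with the block in the fit to the tolDC libraries alone 260 rose and 160 fell, and with a donor term within each cell type 357 rose and 252 fell. Without donor 1 there was 1 call, MEST, which was chosen after its values were seen, and without donor 2 there were 6, or 24 with the block. The leading genes, given as not past the threshold, were AMPD3 (log2 fold change 0.90, edgeR adjusted p = 0.228, and 0.0105 with the block), METTL13 (0.36), GIT1 (0.60) and FAM219A (0.76) upward, and SMAD3 (−1.76), LIPT1 (−1.01), P2RY13 (−1.66) and CCL26 (−1.52; adjusted p = 0.3, and 0.026 with the block) downward. SMAD3 also passed with the block (adjusted p = 0.0105). LILRB4 stood at 0.04 (−0.01 with the block) and FN1 at 0.31. Integrin, matrix and cholesterol synthesis lists lay higher by camera (adjusted p = 0.0139, 0.0304 and 0.0139), each at adjusted p = 0.777 with an estimated correlation. The difference between the 16C5 effects on the 2 coatings reached the threshold for 0 genes in tolDC (edgeR, without and with the block; 191 at an unadjusted p under 0.05; 0 by DESeq2 and by limma-voom), so no gene was shown to respond differently on fibronectin than on PBS.

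The 81 genes were followed through the other comparisons, signed by their direction in tolDC on fibronectin, whose libraries had chosen them. On PBS, whose tolDC libraries did not choose the genes, 81 of 81 moved the same way with 16C5, with a mean signed log2 difference of 0.65 ± 0.23 (SD over donors, n = 3) against 1.17 ± 0.188 on fibronectin. In moDC the counts were 78 of 81 on fibronectin (0.425 ± 0.137) and 74 of 81 on PBS (0.24 ± 0.171). In the macrophages the mean signed differences lay between 0.00303 and 0.118. Fibronectin under control antibody moved 0 of 81 the same way in tolDC (−0.47 ± 0.117), where the control libraries are shared with the choice of genes, and 6 of 81 in moDC (−0.16 ± 0.102), where they are not. Fibronectin under 16C5 gave 0.06 ± 0.054 in tolDC and 0.03 ± 0.0609 in moDC. Of the 81 genes, 77 reached a mean of 1 CPM in tolDC and 74 in moDC, and the means are over these.

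Over 9958 genes of tolDC, which are not independent replicates, the log2 fold changes of 16C5 on the 2 coatings, from separate libraries, had a Pearson correlation of 0.758 across genes, against a mean of 0.000601 in 20 simulated draws without effects. Those of 16C5 on fibronectin and of fibronectin under the control antibody, which share the control libraries on opposite sides, had a correlation of −0.808 against −0.501 simulated, and a covariance of −0.0752 against −0.0245. Those of 16C5 on PBS and of fibronectin, which share the PBS control libraries on the same side, had a correlation of −0.342 against 0.495 simulated, and a covariance of −0.0207 against 0.0243. The draws for 16C5 on the 2 coatings lay between −0.028 and 0.0478. So narrow a range leaves out shifts that many genes share within a library, which real libraries can have. The simulated values show what shared controls alone give and are no test of chance.

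**Figure D3:**
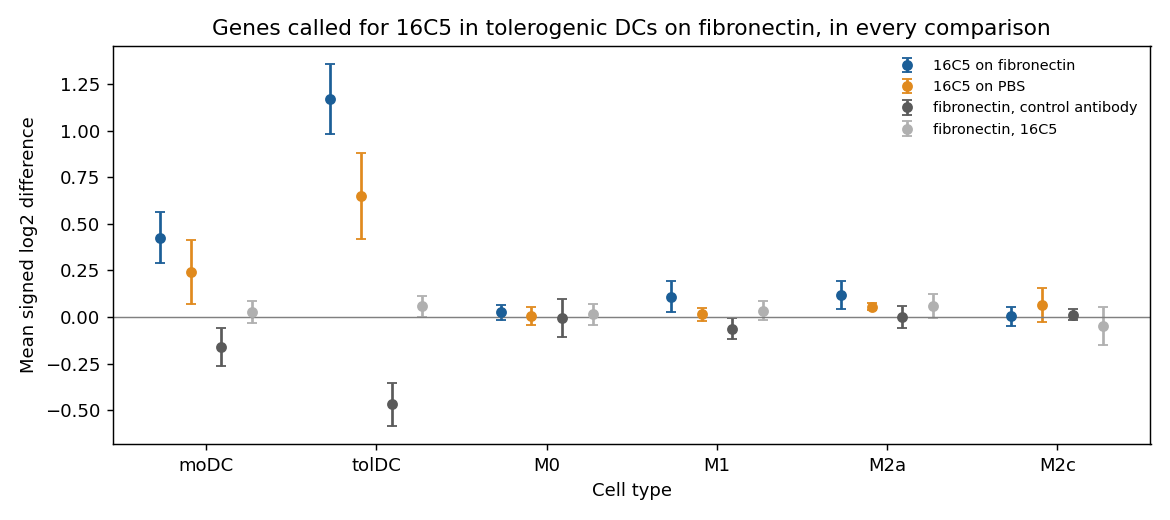
Mean signed log2 difference (y axis) of the 81 genes called for 16C5 in tolerogenic dendritic cells on fibronectin, in every cell type (x axis), for 16C5 on each coating and for fibronectin under each antibody. Points are means over 3 donors and bars ± SD; genes under a mean of 1 CPM in a cell type are left out. For 16C5 on fibronectin the mean was 1.17 in tolDC, the comparison that chose the genes, and 0.425 in moDC.

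In the other 5 cell types 16C5 on fibronectin called no gene in edgeR without a donor term. In moDC 466 genes had an unadjusted p under 0.05 (0 calls by DESeq2 and limma-voom), with 2 calls under the donor block, the amyloid precursor gene APP (0.49) and GUCA1A, and 1 call each without donor 1 (JMY) and without donor 2 (ODF2), all chosen after their values were seen. Other paired fits in moDC called far more, 205 risen and 199 fallen with a donor term within each cell type and 307 and 209 with the block in the fit to the moDC libraries alone. The leading genes there, given as not past the threshold (edgeR adjusted p = 1 for each), were NCKAP1 (1.52), GPR137B (0.37), C7orf60 (0.45) and KIF2A (0.44) upward and CCL26 (−1.56, 10.1 ± 2.94 CPM against 30.8 ± 9.16), PIK3IP1 (−1.05) and SNTB1 (−0.90) downward. In M1 the number at an unadjusted p under 0.05 was 1264 (0 by both tools), in M2a 130 (0 by both), in M2c 65 (0 by both) and in M0 52 (1 by DESeq2, GBP7, chosen after its values were seen, and 0 by limma-voom). In M1, leaving out donor 2 gave 19 calls, and 779 with the donor block, and a donor term within each cell type gave 2, PTPRO (0.75) and UBD (−1.11), chosen after their values were seen. In the fit to all donors the ribosomal protein genes of M1 lay lower with 16C5 (median −0.53, camera adjusted p = 2.32e-08, and adjusted p = 0.965 with an estimated correlation).

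On PBS 16C5 likewise called no gene in these types by edgeR without a donor term or by limma-voom. In moDC edgeR called 9 with a donor term within each cell type and 25 with the block in the fit to that type alone, and 0 with the block over all types. DESeq2 called 1 gene in moDC, M0, M1 and M2a and 0 in M2c. The numbers at an unadjusted p under 0.05 were 99 in moDC, 62 in M0, 37 in M1, 116 in M2a and 153 in M2c. The difference between coatings reached the threshold for 0 genes in these types, with 69, 52, 341, 91 and 158 genes at an unadjusted p under 0.05 in moDC, M0, M1, M2a and M2c (1 call by DESeq2 in M0 and M2a, 0 in the others, and 0 by limma-voom). DESeq2's single calls were GBP7, a gene with few counts, in moDC and M0 and IFI44L in M2a, named after their values were seen, while the one in M1 belongs to the genes never named. In M2a on PBS, interferon response genes lay lower with 16C5 (median −1.01, camera adjusted p = 2.93e-18; adjusted p = 0.15 with an estimated correlation), with 21 of 34 lower adjusted over the list alone and 0 over all genes. The control libraries varied widely, with IFI44L at 1.24 ± 0.896 CPM with 16C5 against 42.5 ± 72.3, ISG15 at 4.16 ± 1.61 against 21.1 ± 28.4, IFIT1 at 5.00 ± 0.86 against 36.2 ± 54.7 and MX2 at 22.0 ± 1.96 against 77.4 ± 97.3. IFI44L and MX2 were higher with 16C5 in 2 of 3 donors and ISG15 and IFIT1 in 1 of 3. Without the control library of donor 1 on PBS the list's direction turned, at camera adjusted p = 0.404 (0.943 with an estimated correlation), and without those of donors 2 and 3 it stood at 0.00504 and 0.00897 with an estimated correlation. For the difference between coatings in M2a, the interferon list lay higher at adjusted p = 4.43e-24 by camera and 0.0211 with an estimated correlation, and at 0.308 and 0.985 without that library of donor 1. With an estimated correlation 5 of 12 fits that left out one library passed. B cell and plasma cell markers lay higher at 0.000962 and 0.0071, and 6 of 12 such fits passed (0.000683 to 0.209). In the first list 13 of 34 passed adjusted over the list alone and in the second 0 of 8, and 0 passed over all genes.

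**Figure D4:**
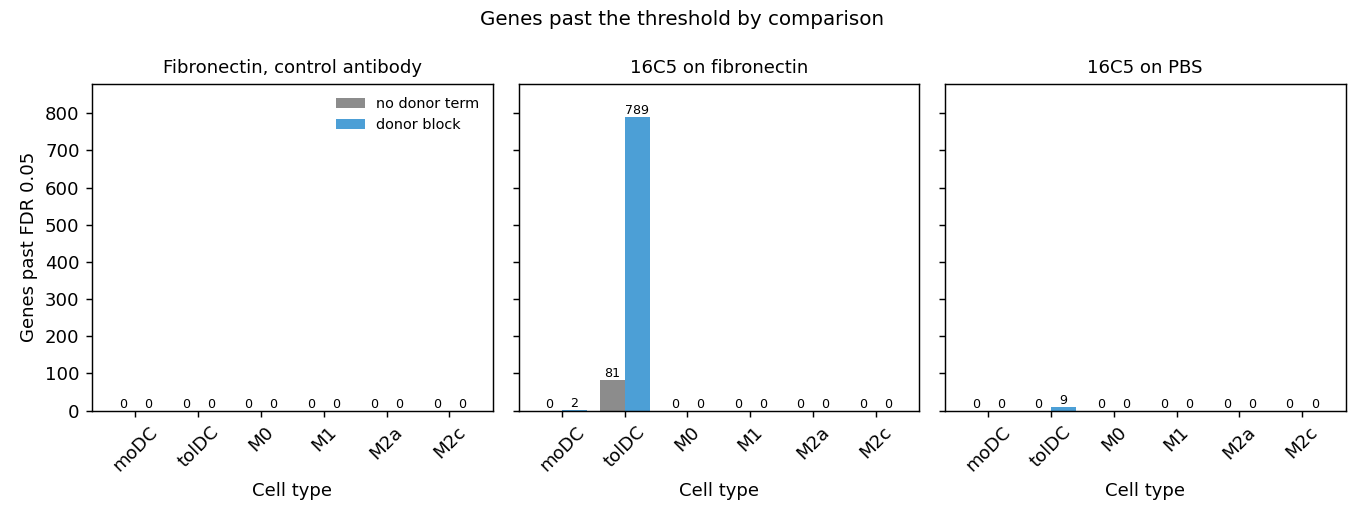
Number of genes past an adjusted p of 0.05 (y axis) in each cell type (x axis) for fibronectin under control antibody, 16C5 on fibronectin and 16C5 on PBS, without a donor term and with the donor as a block. For 16C5 on fibronectin tolDC had 81 and 789 genes and moDC 0 and 2, and on PBS tolDC had 0 and 9. Other paired fits, not drawn, called more genes in moDC, in tolDC on PBS and for fibronectin in tolDC, as given in the text.

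As a mean over the 6 cell types, 16C5 on fibronectin called 0 genes in edgeR (1700 at an unadjusted p under 0.05; 65 by DESeq2 and 0 by limma-voom) and with the donor block 124 rose and 152 fell (922 and 1050 with a donor term within each cell type). The leading genes, given as not past the threshold, were EIF2AK3 (0.18), AMPD3 (0.35), MICAL2 (0.39) and EPT1 (0.24) upward and MSRB2 (−0.35), TMEM150B (−0.49), SMARCD3 (−0.43) and YPEL3 (−0.39) downward. All stood at an edgeR adjusted p of 0.0981 without the block and passed with it, at 0.00517 to 0.0187. LILRB4 stood at −0.10, which was 0.13 without donor 1 (0.12 with the block), and FN1 at 0.49, which was 0.13 without the shallowest library and −0.03 without donor 3. Ribosomal protein genes lay lower (median −0.16, camera adjusted p = 0.000117; adjusted p = 0.964 with an estimated correlation), one of 5 lists called by camera, none of which held with an estimated correlation. Without donor 2 the calls numbered 434, and with the block they numbered 83 without donor 1, 1128 without donor 2 and 2 without donor 3, C3 and HLA-DOA, chosen after their values were seen. A test of whether this effect differed between the 6 cell types called 0 genes (230 at an unadjusted p under 0.05; 2 by limma-voom, AMPD3 and MEST) and 7 with the block (662 with a donor term within each cell type). It called 1 gene without donor 1 (MEST) and 3 without donor 2 (AMPD3, ODF2 and CYBB), all chosen after their values were seen.

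On PBS the mean effect of 16C5 called 0 genes (240 at an unadjusted p under 0.05; 1 by DESeq2, GBP7, and 0 by limma-voom), and a donor term within each cell type called 42. Its leading genes, none past the threshold without or with the block, were NTN1, EPT1, DEPDC4 and SLC35F5 upward and LIPT1, IQCD, FAM50B and P2RY13 downward (edgeR adjusted p = 1 for each). LILRB4 stood at −0.20 and FN1 at −0.19. The mean difference between coatings called 0 genes (139 at an unadjusted p under 0.05; 1 by DESeq2, again GBP7, and 0 by limma-voom). Without donor 2 it called 53, and 269 with the block.

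Fibronectin under the control antibody called no gene in edgeR in any cell type or as a mean when all cell types were fitted together, without a donor term or with the donor block. A donor term within each cell type called 19 risen and 104 fallen genes in tolDC, 5 genes in M1 (PECAM1 upward and ATP2B4, IL7R, NEDD9 and ZNF395 downward) and 46 as a mean, and the block in fits to one cell type called 14 in tolDC and 2 in moDC (DHRS9 and AKAP12, downward). At an unadjusted p under 0.05 there were 45 genes in moDC, 414 in tolDC, 68 in M0, 569 in M1, 74 in M2a, 118 in M2c and 235 for the mean. Each lay below the number expected by chance among all tested genes. The lack of calls without a donor term thus does not show that fibronectin changed no gene. DESeq2 called 1 gene in moDC and M0 (GBP7), in M1 (a gene never named) and for the mean (ISG20L2) and 0 in the others, and limma-voom 2 in M1 (OSMR and HRH2) and 0 in the others. Without donor 2 there was 1 call in M1 (ZNF551), and 7 with the block. Of these genes all but ISG20L2 were chosen after their values were seen. In tolDC the leading genes, given as not past the threshold, were KIF22 (0.70), ABCA7 (0.80), TNFRSF14 (0.63) and OVCA2 (1.63) upward and ISG20L2 (−0.27), EIF2AK3 (−0.37) and REPS1 (−0.35) downward, with PROX1 at 0 counts on fibronectin and 0.0992 ± 0.14 CPM on PBS. For the mean they were LYPD5, WBP1, ELOVL3 and TNFRSF14 upward and ISG20L2, TSPAN2, RNF4 and EIF2AK3 downward, of which ISG20L2 had the smallest adjusted p (−0.14, SE 0.0284, 0.146). LILRB4 stood at −0.16 in tolDC and 0.00 for the mean, and FN1 at −0.47 and −0.13. Oxidative stress and glycolysis genes lay lower in tolDC by camera (medians −0.40 and −0.31, adjusted p = 0.015 each; 0.955 with an estimated correlation). Among all the fibronectin comparisons a list held with an estimated correlation only in M2a, where 8 B cell and plasma cell markers lay lower (camera adjusted p = 0.000144, and adjusted p = 0.00126 with an estimated correlation) at levels such as 0.121 ± 0.112 CPM against 0.30 ± 0.0226 for CD79B, with 0 of 8 past the threshold over all genes or in the list alone. That list passed in 2 of 6 fits that left out one library, and stood at 0.174 and 0.727 without the fibronectin libraries of donors 2 and 3 and at 0.0676 and 0.111 without the PBS libraries of donors 1 and 2. A test of whether the fibronectin effect differed between cell types called 0 genes (47 at an unadjusted p under 0.05; 0 by limma-voom), and 1, C3, chosen after its values were seen, with a donor term within each cell type.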

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

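The donor block and the test between cell types were chosen before the data were examined, while the tests of depth by thinning, of other cell types, of direction in other libraries and of other splits of the libraries, and what each would show, were written down only after the results were seen.

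For 7 genes the effect of 16C5 on fibronectin differed between the 6 cell types in the test of that difference with the donor block. The adjusted p (edgeR) was 0.000149 for KCNE3, 0.00105 for AMPD3, 0.0236 for MEST, 0.0425 for LRRC16A, 0.0466 for C3, and 0.0492 for both KIAA0040 and ZDHHC13. Without the block 0 genes passed, AMPD3 being at 0.105. With the block there were 4, 6 and 2 calls without donors 1, 2 and 3. Of the 7 genes KCNE3 and MEST were among the 4, beside TRIM44 and PHLDA1, chosen after their values were seen, and KCNE3 and C3 were the 2. In tolDC KCNE3, a potassium channel subunit gene, stood at a log2 fold change of −1.05 (SE 0.173), AMPD3 at 1.42 (SE 0.198), MEST at 2.91 (SE 0.574), LRRC16A at 2.73 (SE 0.504), C3 at 2.55 (SE 0.432), KIAA0040 at 0.81 (SE 0.153) and ZDHHC13 at 1.13 (SE 0.166), and each passed there (n = 3 donors). In moDC KCNE3 stood at −0.44, AMPD3 at 0.53, LRRC16A at 1.03, C3 at 0.83, KIAA0040 at 0.08, ZDHHC13 at 0.08 and MEST at −0.08, and none passed. In M0 the values lay between −0.27 (MEST) and 0.15 (ZDHHC13), and in M2c between −0.05 and 0.18. MEST in M1 stood at 0.96 (SE 0.679).

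The first pattern weighed is that 81 genes passed for 16C5 in tolDC on fibronectin, among 10 splits of the 6 libraries of which the real one gave 81 and the highest other 1, too few splits for a share under 0.05. After thinning the tolDC libraries to equal depth, 60 of the 81 passed with the same sign. This argues against unequal depth as the whole cause. The correction for GC content and gene length was run only with the donor block. It kept 80 of the 81, against 81 with the block alone. Their median signed log2 fold change was 0.965, against 0.976 with the block alone. This argues against a trend with GC content or gene length as the cause of these 81 fold changes. The same correction raised the number of calls in this comparison over that with the block alone, as given below. Such trends are thus not excluded for other genes. For the 51 that rose, 0 of 3 marker lists rose by more than the 16.9 CPM median of those genes. These were T and NK cells (4.02 ± 4.78 CPM), B and plasma cells (−1.88 ± 3.59) and platelets and red cells (0.288 ± 0.174). T and NK markers still rose in 3 of 3 donors, from 3.21 ± 1.93 CPM in the control. Platelet and red cell markers did so too, from 1.09 ± 0.174 CPM, and B and plasma cell markers rose in 2 of 3. Other genes of such cells can be more abundant than the markers, so more of these cells cannot be told apart from a response of tolDC. The same holds for more granulocytes, fibroblasts, endothelial or epithelial cells, monocytes or macrophages. Their markers, at 99.4 CPM or more in the control (monocyte genes 4430), would hide a small share, and no list of unpolarised macrophage markers was fixed. For the 30 that fell, whose median change was −11.5 CPM, fewer such cells cannot be told apart from a response of tolDC, because granulocyte markers (−34.6 ± 18.8 CPM) and fibroblast, endothelial and epithelial markers (−15.5 ± 11.1) fell by more, 2 of 5 lists, and dendritic cells may express members of both lists. A response to blocking ILT3 stays open, and without donor 3, 2 genes passed (28 of the 81 with the block), against 132 without donor 2 and 45 without donor 1, a dependence whose cause was not tested.

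The second pattern is that these genes leaned the same way with 16C5 on PBS and in moDC. In libraries that did not choose the genes, 9 of 9 donor differences lay above 0 (mean 0.438). An exact two-sided sign-flip test on them gave p = 0.00391 of 512 flips, also after Benjamini-Hochberg adjustment over 2 tests. It treats the 9 as independent, although they come from 3 donors and speak for these donors only. Flips of whole donors could not reach 0.05 with 3 donors, so a chance direction is not excluded. On these 81 genes, an effect of equal size in every cell type, as from the antibody or its handling, is argued against. The mean signed difference was 0.0491 in the 4 macrophage types, against 0.333 ± 0.153 in moDC. The macrophage value was itself above 0 (10 of 12 differences, exact sign-flip p = 0.00293, which again treats differences from 3 donors as independent). For these 81 genes, an effect that follows LILRB4 RNA over all cell types is argued against by M1, at 0.0611 with more LILRB4 RNA than moDC. Genes chosen in tolDC cannot show whether M1 or another macrophage type responded through other genes. On fibronectin 1264 genes had an unadjusted p under 0.05 for 16C5 in M1 and 466 in moDC (edgeR). Between the dendritic cell types the order did go with LILRB4 RNA, at 0.649 in tolDC and 0.24 in moDC on PBS, although tolDC chose the genes. A response to blocking ILT3 and an antibody or handling effect both stay open, as only 1 control antibody was used. The latter could be restricted to dendritic cells or act through other genes in macrophages.

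The third pattern is that fibronectin under the control antibody moved the 81 genes opposite to 16C5. Sharing of control libraries as the whole cause is argued against in moDC, whose libraries did not choose the genes and where 6 of 81 moved with the 16C5 direction, with 3 of 3 donors below 0. A deviation of the fibronectin cultures with control antibody alone cannot be told apart from an effect of fibronectin that 16C5 removes, since under 16C5 fibronectin gave 0.0269 ± 0.0609 in moDC, which both allow. Engagement of ILT3 by fibronectin stays open as well, with 0 genes past the test between coatings.

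Other splits of the libraries were counted for every comparison. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Between cell types 1 of 10 splits gave as many genes as the real one, with 1978 against a highest other of 0 in tolDC over moDC, 5543 against 1 in M1, 858 against 26 in M2a, 2117 against 0 in M2c and 5438 against 3 in moDC over M0. Within a cell type, apart from the 81, the real count was 0, so that 10 of 10 splits gave as many, as any split must, and the share says nothing about chance. The highest other count was 3 for fibronectin in moDC, 2 in tolDC and M2a and 185 in M1, 765 for 16C5 on fibronectin in M1, and 1, 6 and 2 for 16C5 on PBS in moDC, tolDC and M1, with 0 in the others. The 185 and 765 point to a structure of the samples, since the splits that part all 3 donor pairs, as the real one does, gave at most 0 apart from the real ones. For the means and differences 50 regroupings were drawn, the real one included, and 50 of 50 gave as many as the real 0, again as any must, so the share says nothing about chance there. The highest other counts were 1836, 1073, 39, 1755, 463 and 227 for the difference between coatings in moDC, tolDC, M0, M1, M2a and M2c, 505 for its mean, 154 for the mean effect of 16C5 on fibronectin, 0 for those of fibronectin and of 16C5 on PBS, and 455 and 378 for the differences between cell types. These regroupings moved libraries across donors within a cell type, so differences between donors can enter the counts. Regroupings within donors, fitted with the donor block, gave a highest other count of 0 for the mean difference between coatings. They gave 0 as well for the mean fibronectin effect and for its difference between cell types. With the donor block only the real grouping, 1 of 50, reached the 276 genes of the mean effect of 16C5 on fibronectin (highest other 1). It alone also reached the 7 genes of the difference of this effect between cell types (highest other 0). A share of 1 in 50 is the smallest these draws can give, and it was not adjusted over the comparisons drawn. All regroupings kept the dispersion of the fit to the real groups. Chance is thus argued against for both but not excluded. The same draws gave up to 219 genes for the mean effect of 16C5 on PBS, whose real count was 0, so that a regrouping within donors can call many genes. Without donor 3 the 276 were 2.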

How the results depend on the processing

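The donor term within each cell type, the fit without the shallowest library, the thinned libraries and the tests of gene lists without one library at a time were chosen after the data were seen. The other settings were chosen before the data were examined. Below, gene counts are calls at an adjusted p under 0.05, and where a setting is not named for a comparison its count lay within 1.5 times that of the fit to all libraries without a donor term. For each changed count the cause was not tested, except that fewer libraries enter the fits to own cell types and those without a donor.

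With the donor block 16C5 on fibronectin called 2 genes in moDC, 789 in tolDC and 276 as a mean, its difference between cell types 7, and 16C5 on PBS 9 in tolDC. Between cell types there were 3580 calls in tolDC over moDC, 1994 in M2a and 3498 in M2c over M0. The block also raised the calls in M1 and moDC over M0, to 7099 and 7052, which lie within 1.5 times. Every other comparison stayed without calls. With the block and the GC and length correction the counts first given here, up to the one in M2c, were 2, 1204, 455, 26, 20, 4177, 2505 and 4089. With DESeq2's Wald test and the block they were 2, 945, 602, 13, 3651, 2177 and 3644 (the difference between types was not run with DESeq2), and it called 1 gene for fibronectin and 1 for 16C5 on PBS in M1, 2 for 16C5 on fibronectin in M1, 3 for 16C5 on PBS and 2 for the difference between coatings in M2a, and 2 for the mean fibronectin effect. A donor term within each cell type gave, for 16C5 on fibronectin, 404 in moDC, 2553 in tolDC, 2 in M1, 1972 as a mean and 662 for the difference between types, for 16C5 on PBS 9 in moDC, 609 in tolDC and 42 as a mean, and for fibronectin 123 in tolDC, 5 in M1, 46 as a mean and 1 for the difference between types. In fits to the own cell types with the block, fibronectin called 2 in moDC and 14 in tolDC, 16C5 on fibronectin 516 and 2285, 16C5 on PBS 25 and 420, and there were 4833 in tolDC over moDC, 4317 in M2a and 4415 in M2c. Without the block such fits gave 2 for 16C5 on fibronectin in tolDC and 1453 in M2a.

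DESeq2's Wald test without the block called 216 genes for 16C5 on fibronectin in tolDC, 65 as a mean, and 1 each for fibronectin in moDC, M0, M1 and as a mean, 16C5 on PBS in moDC, M0, M1, M2a and as a mean, 16C5 on fibronectin in M0, and the difference between coatings in M0, M2a and as a mean. With limma-voom 16C5 called 193 on fibronectin and 10 on PBS in tolDC, fibronectin 2 in M1, and the difference between types 2. With library size alone fibronectin called 1 gene in moDC, LYPD5, and 16C5 on fibronectin in tolDC 74 genes, of which 39.2% were higher against 63.0%. No scaling moved the median of all genes by more than 0.1 on the log2 scale. Without a filter 16C5 on fibronectin in tolDC called 45 genes, and 40 had an absolute log2 fold change of at least 1. Of the 81 genes there, 81 were kept with the block, 80 with DESeq2, 71 with limma-voom, 79 with DESeq2 size factors, 57 with library size alone, 45 without a filter, 80 with a stricter filter, 69 without the shallowest library, 60 at equal depth and 2 in the fit to tolDC alone (80 with the block). Without donors 1, 2 and 3, 23, 33 and 2 were kept, and 62, 65 and 28 with the block. The median signed log2 fold change of the 81 lay between 0.915 and 1.09 in all of these, against 0.975, on libraries that had taken part in choosing the genes.

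Without each donor in turn, calls ranged for 16C5 on fibronectin from 2 to 132 in tolDC (with the block 367, 660 and 65 without donors 1, 2 and 3), 0 to 1 in moDC (0 to 2), 0 to 19 in M1 (0 to 779), 0 to 434 as a mean (83, 1128 and 2) and 0 to 3 for the difference between types (4, 6 and 2). For 16C5 on PBS in tolDC they ranged from 0 to 6 (0 to 24), for fibronectin in M1 from 0 to 1 (0 to 7) and for the mean difference between coatings from 0 to 53 (0 to 269). Between cell types they ranged from 653 to 1526 in tolDC over moDC (1672 to 2593), 3789 to 5207 in M1 (5439 to 6426), 220 to 1144 in M2a (746 to 2062), 1011 to 1963 in M2c (2156 to 2907) and 3104 to 5278 in moDC over M0 (4908 to 6522). Without the shallowest library they numbered 1937, 2124 and 5427 in tolDC, M2c and moDC. LILRB4 in tolDC over moDC ranged from 1.55 to 2.02 (1.56 to 2.08) and lost its call without donor 3, at 1.79 (adjusted p = 0.12, edgeR). Gene lists called for 16C5 on fibronectin in tolDC, 6 by camera, numbered 3 to 9 (1 to 8), 0 with an estimated correlation with or without the block and 0 with fry, 10 without a filter, 10 in the fit to own cell types, and 11 there with the block and with the donor term within types.

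Of 4978 values of the 270 results on single genes, 4541 kept direction and side of the threshold, 151 lost the call, 272 gained it and 14 changed sign, 0 of them called. LILRB4 changed sign for 16C5 on PBS in tolDC (−0.005532 with the block, −0.02683 to 0.1977 without each donor in turn, being −0.01165 without donor 3, and with the block −0.07016 and −0.07523 without donors 1 and 3). It did so for the mean fibronectin effect (−0.008051 with the block, −0.008812 with DESeq2 and the block, −0.03311 to 0.03818 without each donor in turn, and −0.04527 without donor 3 with the block) and for the mean of 16C5 on fibronectin (−0.2542 to 0.1313 without each donor in turn, and 0.121 without donor 1 with the block). FN1 changed sign for that mean (−0.03445 to 0.6693, and −0.0471 without donor 3 with the block) and in M2c over M0 (−1.624 to 0.2125). Interferon genes in M2a turned without the PBS control library of donor 1, for 16C5 on PBS (adjusted p = 0.943 with an estimated correlation, and 0.00504 to 0.943 without each of the 6 libraries in turn) and for fibronectin (0.143, and 0.0625 to 0.969). Depth ran from 3968752 to 58529141 counts per library. In simulated counts the test without the block found 23.9% of the genes changed 1.5-fold, so smaller changes were mostly not detectable with 3 donors.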

Other observations

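The lists in this part were chosen after their results were seen, although the lists themselves were fixed before the data were examined.

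Of 19 cholesterol synthesis genes, of which 10 fell in tolDC against moDC, 9 rose in M2a, 15 in M1 and 12 in M2c against M0, and the list was past the threshold with an estimated correlation in M2a alone and there not with the donor block. In M2a 9 of 19 rose over M0 (12 adjusted over the list alone, 0 fell; camera adjusted p = 3.07e-11, adjusted p = 0.0399 with an estimated correlation and 0.0954 with the donor block as well, and 0.0568, 0.0618 and 0.158 without the M0 libraries of donors 2 and 3 and the M2a library of donor 2), including FDPS (log2 fold change 0.75, edgeR adjusted p = 0.00117), CYP51A1 (0.64) and MVK (0.82). In M1 15 of 19 rose (18 adjusted over the list alone; adjusted p = 0.215 with an estimated correlation), with LSS at 433 ± 123 CPM against 119 ± 26.7 and MVD at 120 ± 10.3 against 45.4 ± 5.35. In M2c 12 of 19 rose (16 adjusted over the list alone; adjusted p = 0.0905 with an estimated correlation). The metallothionein genes MT2A and MT1F, whose products bind zinc and copper, rose in M1 over M0, with MT2A at 2330 ± 838 CPM against 9.42 ± 3.39 (7.95, edgeR adjusted p = 4.34e-11) and MT1F at 195 ± 62 against 0.655 ± 0.481, although near-identical copies could share their reads. Of the 16 genes of the metallothionein and oxidative stress list 9 rose and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 0.215 with an estimated correlation).

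Among 17 genes of the ILT3 family and its signalling, LILRA1 rose with LILRB4 in tolDC over moDC, to 16.7 ± 10.9 CPM from 2.83 ± 1.81 (2.57, edgeR adjusted p = 0.00186). In M1 over M0 LILRB1 rose to 358 ± 72.4 CPM from 58.8 ± 14.2 (2.61), the phosphatase gene PTPN6 rose by 0.69, and the activating receptor gene LILRA5 fell to 8.22 ± 2.48 from 91.9 ± 2.51 (−3.48, adjusted p = 1.98e-07). Reads of the LILR genes could be shared between near-identical copies. Heat shock genes lay higher in M2a than in M0 (median 0.42, camera adjusted p = 5.1e-05, adjusted p = 0.0229 with an estimated correlation and 0.0769 with the donor block as well, and 0.0648 and 0.0649 without the M0 library of donor 1 and the M2a library of donor 3). Of its 11 members HSPH1 (1.53) and HSPA8 (0.43) rose over all genes and 5 adjusted over the list alone, among them DNAJA1 (0.43) and HSP90AA1 (0.42).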
